A study of Mus musculus with 3 samples.

How the data were processed

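The series holds polyA-selected RNA sequencing of effector memory CD4 T cells, per the labels, from 1 male mouse of a CD45 congenic C57BL/6 line (BoyJ) aged 5 months. The labels give 1 biosample and number its 3 libraries as technical replicates 1, 2 and 3, and those numbers name the libraries here. The cells form 1 group, so no comparison between conditions was possible, and SDs measure only the spread between libraries labelled as 1 biosample. Chi-square p-values set the differences between these libraries against counting error. Permutation p-values compare lists of genes by their means over the libraries and carry no spread between libraries. The gate used to sort the cells is not given in the sources used here.

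Each library came with a gene table and a transcript table on mouse build mm10 with GENCODE M21 annotation, per the file headers. The deposited expected counts are estimates that share a read among the transcripts it matches, and they need not be whole. The deposited TPM values are transcripts per 1e6 transcripts and the deposited FPKM values are fragments per kilobase and 1e6 fragments, each scaled within its library by the authors. In the transcript tables, the deposited percent values give each transcript's share of its gene. A further gene table on GENCODE M4 annotation holds whole-number counts, which the authors deposited without a header. The aligner and the quantifier are not given in the sources used here. Effective lengths in the deposited tables equal the transcript length less the value that reads of 50 bases give, for 100% of transcripts. Whether counting used strand is not given either, so genes that overlap on opposite strands are reported as uncertain.

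The M21 tables have 81881 rows, of which 55536 carry an Ensembl gene ID and 97 are spike-in sequences. All 55536 IDs were found in the GENCODE M21 annotation, which supplied symbols, gene classes and coordinates on GRCm38, the same assembly as mm10. The 26248 rows with a numeric ID and the spike-in rows were left out of library sizes and tests. Gamma-delta constant genes listed as Trgc1, Trgc2 and Trgc4 were matched to the annotation's Tcrg-C1, Tcrg-C2 and Tcrg-C4 through RefSeq synonyms.

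A gene was called detected at a TPM of at least 1 in each library. Library agreement was measured with correlations across genes of log2(TPM + 1) and with the common coefficient of variation of edgeR 4.0.16 in R 4.3.3. That fit had an intercept only, used expected counts rounded to whole numbers, and applied TMM scaling and the filterByExpr filter. No quasi-likelihood test was run, since the design has 1 group. Genes with at least 30 rounded counts in total were tested for homogeneity over the libraries with Pearson's chi-square test, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Calls from that test compare these libraries and not conditions. Two-sided permutation tests with 100000 resamples of list labels over genes compared the mean log2(TPM + 1) of gene lists. Genes are not independent replicates, so those p-values describe the lists. Each list's median was set against 10000 random lists of the same size drawn from genes with a TPM above 0, but many lists exceeded all of these, so that percentile does not rank the lists. Receptor V gene counts were compared with chi-square tests and with the total variation distance, the summed absolute difference in shares divided by 2. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used. A floor of 3 counts was taken as the limit that a count of 0 allows, and it covers counting error only, since the reads carry no molecular identifiers in these tables.

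The steps were tested on simulated data. With counts drawn around the real means of 13185 genes and 50 genes changed in library 1 at each fold, the chi-square test called 34.0% of those changed 1.2-fold and 72.0% of those changed 1.5-fold. It called 78.0% of those changed 2-fold, 100% of those changed 4-fold and 0.0616% of unchanged genes. The simulated counts held counting error only, whereas the real counts had a median overdispersion of 19.8. These rates therefore do not carry over to the real counts. For 13115 genes simulated with coefficients of variation of 0.05, 0.2 and 0.4, edgeR returned 0.0497, 0.198 and 0.390. The permutation test of 2 lists passed 4.5% of simulated pairs with no difference and 98.0% of pairs with a log2 difference of 2.5. Smaller differences were not simulated, so the power of the test to find them is not known.

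The 31 gene lists, the tests of the main results, their alternatives and the rule for named genes were fixed before the data were examined. The tests of explanations and 1 further alternative were written later. The rule named the 10 most abundant genes outside mitochondrial and ribosomal protein genes, the 10 most abundant transcription factors and receptors of the lists, and the 3 highest detected and the undetected members of each list. It also named the 10 varying genes with the largest ratio between libraries at a mean TPM of at least 5, list members that varied, a set of lineage genes and the 5 leading V genes of each chain. Of the list members that varied, and of the undetected markers of other cells, only examples are named here and the rest are counted. Some genes that the rule names are not reported here. Which list members count as transcription factors or receptors was settled after their values had been seen. Alternatives left out each library in turn and changed the TPM threshold, unit, pseudocount, scaling, count minimum, reference gene and gene table. The M4 table holds counts without lengths, so it served only where counts suffice.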

Results

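Gene expression was measured in effector memory CD4 T cells, antigen-experienced helper T cells that circulate through tissues, from 1 male mouse aged 5 months. The 3 libraries are labelled technical replicates of 1 biosample, so each SD below is taken as spread between libraries and no animals were compared. Expected counts on annotated genes came to 17474991 in library 1, 15303615 in library 2 and 16882311 in library 3. A TPM of at least 1 was reached in every library by 11694 genes, of which 9900 were protein-coding. The separate counts were 12462, 13483 and 13560 genes in libraries 1, 2 and 3.

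The cells carried the transcripts of alpha-beta T helper cells. Trac, the alpha chain constant gene on chromosome 14 (54220521 to 54224206 in GRCm38), had a mean TPM of 4687 ± 1937 (SD, n = 3). Cd4, on chromosome 6 (124864692 to 124888221), stood at 444 ± 153 (SD, n = 3), with 269 in library 1 against 541 and 523 in the other libraries. Cd8a had 3 counts over all libraries and Cd8b1 a mean TPM of 8.18 ± 2.57 (SD, n = 3). All 22 pan T cell genes were detected, with a median TPM of 578, led by Trac, Trbc2 at 2363 ± 132 (SD, n = 3) and Lck, the proximal receptor kinase, at 1487 ± 748 (SD, n = 3). In libraries 2 and 3 alone Lck averaged 1057, below Ptprc at 1458 and Trbc1 at 1093. All 5 CD4 lineage genes were detected, among them Cd40lg at 518 ± 142 (SD, n = 3), which encodes CD40 ligand. The delta chain constant gene Trdc had a mean TPM of 0.397 ± 0.185 (SD, n = 3), and no gamma-delta marker was detected. Of 5 sex-linked genes 4 were detected, with Ddx3y at 227 ± 19.0 and Eif2s3y at 131 ± 14.3 (SD, n = 3), while Xist, the X-inactivation RNA, had 3 counts in all.

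**Figure D1:**
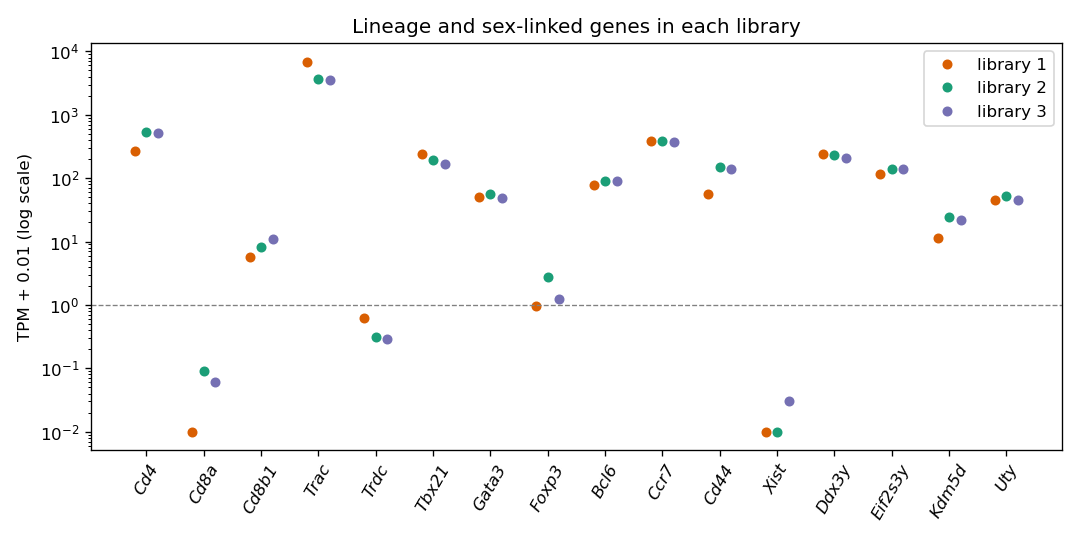
Points give the TPM of each lineage or sex-linked gene in libraries 1, 2 and 3, with 0.01 added and a log axis, and the dashed line marks a TPM of 1. Cd4, Trac, Tbx21 and Ccr7 lie above 100 in every library, and Cd8a and Xist lie below 1.

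Genes linked to effector memory and genes linked to naive and central memory cells were both abundant. Of 28 effector memory genes 27 were detected, with a median TPM of 129, and the exception was Itgae. The highest were Crip1 at 1221 ± 188, Itgb1, an integrin chain, at 923 ± 82.4, and the chemokine gene Ccl5 at 907 ± 267 (SD, n = 3). Of 20 naive and central memory genes 18 were detected, with a median TPM of 111, and Igfbp4 and Ccr9 were not. Tcf7, a transcription factor of naive and memory T cells on chromosome 11 (52252371 to 52283014), reached 1007 ± 312 (SD, n = 3). The egress receptor S1pr1 stood at 708 ± 60.9 and Klf2, a factor that promotes S1pr1 expression, at 692 ± 254 (SD, n = 3). The lymph node homing receptor gene Ccr7, on chromosome 11 (99144196 to 99155077), stood at 381 ± 8.18 (SD, n = 3). Cd44 had a mean TPM of 116 ± 51.6 (SD, n = 3). The effector memory list exceeded the naive list by 0.49 in mean log2(TPM + 1), a difference that did not pass a two-sided permutation test over genes (p = 0.528). The power of that test at a difference of this size was not simulated, so the lists are not shown to be equal.

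Among helper programmes, genes of the Th1 list were the most abundant as a group. All 13 members were detected, with a median TPM of 199.97, led by Bhlhe40 at 619 ± 79.6, Ifng, encoding interferon gamma, at 412 ± 87.7, and Stat4 at 342 ± 46.0 (SD, n = 3). Tbx21, the gene of the Th1 factor T-bet on chromosome 11 (97098071 to 97115331), stood at 199.97 ± 35.8 (SD, n = 3). The follicular helper list followed, with 13 of 14 members detected and a median of 71.4, including Icos at 858 ± 130.0, Slamf6 at 323 ± 74.1 and Bcl6, its lineage factor, at 86.4 ± 6.40 (SD, n = 3). Ascl2 was its undetected member. Of the regulatory T list 13 of 17 were detected, with a median of 14.2, and Tnfrsf4 at 803 ± 461, Tnfrsf18 at 452 ± 149 and Rgs1 at 284 ± 78.2 were highest (SD, n = 3). Foxp3, the regulatory T cell factor, had TPM values of 0.950, 2.70 and 1.23 in libraries 1, 2 and 3, and Ebi3, Lrrc32 and Ikzf4 also missed detection.

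Th2 and Th17 genes were fewer. The Th2 list had 7 of 13 members detected and a median of 3.17, with Il4ra at 321 ± 113, Stat6 at 193 ± 19.4 and Gata3 at 51.7 ± 4.08 (SD, n = 3). Il4 stood at 3.17 ± 1.201 (SD, n = 3). Il5, Ccr4, Il17rb, Il24, Ptgdr2 and Il13 were not detected, and Il13 had no count, which allows a TPM of up to 0.241, 0.292 and 0.251 in libraries 1, 2 and 3. The Th17 list had 7 of 13 detected and a median of 3.12, with Batf at 487 ± 3.23, Rora at 404 ± 41.4 and Stat3 at 324 ± 56.9 (SD, n = 3), genes that other T cells also use. Il17a had 1 count in all, and Il17f, Il22, Il23r and Il1r1 were not detected either.

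The Th1 list exceeded the Th2 list by 4.30 in mean log2(TPM + 1) (adjusted p = 0.0061, two-sided permutation test over genes, Benjamini-Hochberg over 10 pairs). It exceeded the Th17 list by 4.05 (adjusted permutation p = 0.0099) and the regulatory T list by 2.57 (adjusted permutation p = 0.0305). The follicular helper list lay above the Th2 list by 3.08, since Th2 minus follicular helper was -3.08 (adjusted permutation p = 0.0241), and Th17 minus follicular helper was -2.83 (adjusted permutation p = 0.0405). Th1 minus follicular helper was 1.22 and did not pass (adjusted permutation p = 0.214). With only members at a mean TPM of at least 1, which drops 6 Th2, 6 Th17, 1 regulatory T and 1 follicular helper member by the value compared, 0 of the 10 pairs passed. Th1 minus Th2 was then 2.24 (adjusted permutation p = 0.225) and Th1 minus regulatory T 2.34 (adjusted permutation p = 0.206, 0.0206 before adjustment), so the latter call ended with little change in the difference.

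**Figure D2:**
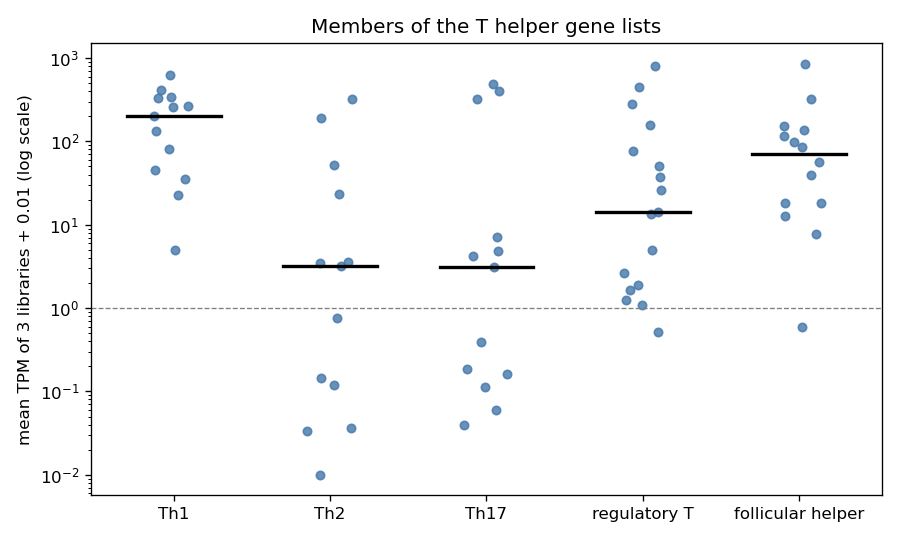
Each point is a member of a helper list, placed by its mean TPM over 3 libraries with 0.01 added on a log axis, and the black bar is the list's median. The Th1 median is 199.97 and the Th2 and Th17 medians are 3.17 and 3.12, with the dashed line at a TPM of 1.

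Immediate early and stress genes were abundant. All 26 members were detected, with a median TPM of 493. Junb, an AP-1 subunit on chromosome 8 (84974484 to 84978718), had a mean TPM of 9164 ± 4868 (SD, n = 3), Nr4a1, a gene induced by receptor signalling, 2839 ± 1079, and Jund 2387 ± 1269 (SD, n = 3). Of the 10 most abundant genes outside the mitochondrial and ribosomal protein classes, Tmsb4x stood at 10489.8 ± 369, H2-K1 at 10481 ± 1723, H2-D1 at 5154 ± 305 and Hspa8 at 5106 ± 2090.2 (SD, n = 3). Malat1, a nuclear long noncoding RNA, stood at 6430.2 ± 2987 (SD, n = 3). Gm37376 at 8463 ± 3651 (SD, n = 3) lies within Malat1 on the opposite strand, so the values of Malat1 and Gm37376 are uncertain. Gm1821 at 5050.2 ± 4371 (SD, n = 3) is a processed pseudogene, so its value is uncertain too. Ubb, a ubiquitin gene, stood at 5913 ± 5223 (SD, n = 3). In libraries 2 and 3 Ubb averaged 2897 and Gm1821 2527, below B2m and Eef1a1, so their places among these 10 rest on library 1. The remaining member, CT010467.1, is annotated as ribosomal RNA and had TPM values of 283, 7709.9 and 9183 in libraries 1, 2 and 3. The highest transcription factors and receptors of the lists were Junb, Trac, Nr4a1, Jund, Trbc2, Klf6, Ptprc, Trbc1, Cd2 and Tcf7.

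Cytokine, cytotoxic and inhibitory receptor genes were partly represented. Of 24 cytokine genes 16 were detected, led by Ltb at 1104 ± 700.2 (SD, n = 3), Ccl5 and Ifng. Library 1 put Ltb first, since its mean TPM in libraries 2 and 3 was 700.2 against 1053 for Ccl5. No count was found for Il3, Il9 and Il13. Il5, Il6, Il17a, Il17f and Il22 were not detected either. Of 12 cytotoxic genes 10 were detected, led by Nkg7 at 662 ± 236, Fasl at 285 ± 169 and Ctsw at 131 ± 43.3 (SD, n = 3), without Gzma and Gzmc. Of 10 inhibitory receptors 8 were detected, led by Ctla4 at 159 ± 52.3, Tigit at 155 ± 41.4 and Vsir at 146 ± 30.2 (SD, n = 3), without Lag3 and Havcr2. In libraries 2 and 3 alone Tigit averaged 132, below Pdcd1 at 155. Of 17 homing and egress genes 12 were detected, led by Selplg at 831 ± 190.0, S1pr1 and Itgb7 at 705 ± 214 (SD, n = 3), without S1pr5, Itga2, Itgae, Ccr9 and Ccr10. Of 28 proliferation genes 14 were detected with a median of 2.09, led by the replication genes Pcna at 166 ± 17.4, Mcm6 at 79.8 ± 22.7 and Mcm4 at 60.02 ± 8.82 (SD, n = 3), while Mki67 and the mitotic genes Birc5 and Plk1 were not detected. Nor were Ccna2, Ccnb1, Ccnb2, Bub1, Aurkb, Cenpe, Cenpf, Tpx2, Ube2c, Nusap1 and Kif11.

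Markers of other cell types were low apart from a few genes. Of 95 markers in 10 lists, 18 were detected and 20 had no count in any library. Of these, 11 reached 1% of the mean TPM of Cd3e, and 7 did with Ptprc as the reference. Igkc, the kappa light chain constant gene on chromosome 6 (70726435 to 70726966), stood at 901 ± 149.7 and Ighm at 648 ± 114, as 2 of the 5 detected among 14 B cell markers, while Cd79a, Cd79b, Ms4a1 and Pax5 were not detected (SD, n = 3). Among the plasma cell markers, Jchain stood at 66.0 ± 23.4 and Sdc1 at 1.51 ± 0.397 (SD, n = 3), and the remaining 6 were not detected. Pecam1, also found on T cells, stood at 64.7 ± 15.9 and Epcam at 3.44 ± 0.594 (SD, n = 3), as the 2 detected of 11 stromal, endothelial and epithelial markers. Of 11 dendritic cell markers 5 were detected, led by Cd74 at 25.4 ± 9.48, and of 13 monocyte and macrophage markers 2, Ms4a6c at 9.34 ± 0.307 and Cd68 at 4.72 ± 1.42 (SD, n = 3). Of 9 NK and NKT markers 1 was detected, Klrb1c at 8.68 ± 0.823 (SD, n = 3). None of the 12 neutrophil and mast cell markers or the 10 erythroid and platelet markers was detected.

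Library 1 differed from the others across much of the transcriptome. Its Junb TPM was 14759.8 against a mean of 6366 in libraries 2 and 3, its Trac 6922 against 3569.9 and its Ubb 11944 against 2897. It was lower for Eef1a1, a translation elongation factor gene, at 974 against 4040.1, for B2m at 2028 against 6318 and for Actb at 429.9 against 2142. The ribosomal RNA gene CT010467.1 was lower still, with a log2 ratio of -5.10, and Mir6236 had TPM values of 5.03, 1054 and 1490.1 in libraries 1, 2 and 3. The median log2 ratio of library 1 to the other libraries was -1.06 over the 10 housekeeping genes, all detected, and 7 of these were lower. Mitochondrial genes took 0.781% of the counts in library 1 against 1.76% and 2.00%, and ribosomal protein genes 1.05% against 2.23% and 2.82%. The immunoglobulin share was 0.121% against 0.0881% and 0.0910%, and the 50 most abundant genes took 12.7% ± 0.773 (SD, n = 3). That share depended on the table and unit: these genes took 18.9% of TPM, and the 40 of them in the M4 table took 0.755% of the M4 counts and 10.6% of the M21 counts. Haemoglobin genes took 0.000143% ± 0.000187 (SD, n = 3).

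Counts differed between the libraries beyond sampling noise for 9965 of 13177 genes (75.6%, chi-square test, adjusted p below 0.05). The chi-square test covers counting error only and takes reads as independent molecules. Of these genes, 2704 were higher in library 1 than in both others and at least 1.5-fold above the others' geometric mean. In the same way, 3407 were lower. Counts of varying list genes compare library 1 with that geometric mean only. Scaled by the median overdispersion of 19.8, the number of genes varying between libraries was 2903. Libraries 2 and 3 alone differed at 1991 of 12468 genes, or 16.0%, so neither is the other deposited again. The common coefficient of variation was 0.334 over all libraries, 0.0724 for libraries 2 and 3, and 0.407 and 0.402 for library 1 with library 3 and with library 2. Spearman's correlation across detected genes, which are not independent replicates, was 0.990 for libraries 2 and 3 and 0.926 and 0.925 for the pairs with library 1. Across all genes it did not set library 1 apart, at 0.832 for libraries 2 and 3, 0.846 for 1 and 2 and 0.828 for 1 and 3. Pearson's correlation of log2(TPM + 1) across all genes was 0.987 for libraries 2 and 3 and 0.972 for each pair with library 1. Of the effector memory genes, 24 of 28 varied, or 25 adjusted over the list alone, with 5 at least 1.5-fold higher in library 1 (Fasl and Cxcr6 among them) and 9 lower, such as S100a4 with TPM values of 23.2, 178 and 224. Of the naive and central memory genes, 18 of 20 varied, and also 18 adjusted over the list alone, with 10 lower in library 1 and Klf3 higher. All 13 Th1 genes varied, likewise adjusted over the list alone, and Runx3 and Eomes were at least 1.5-fold lower in library 1. The largest ratios at a mean TPM of at least 5 were those of Gm15459, Trav7d-2, Zc3h11a, Trav7-2, Gm14586, Bnip3l-ps, Mir6236, Gm28661, Gm4294 and Gm6361. These include pseudogenes and V genes with near-identical copies, whose estimated counts can be assigned to either copy, so their ratios are uncertain.

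**Figure D3:**
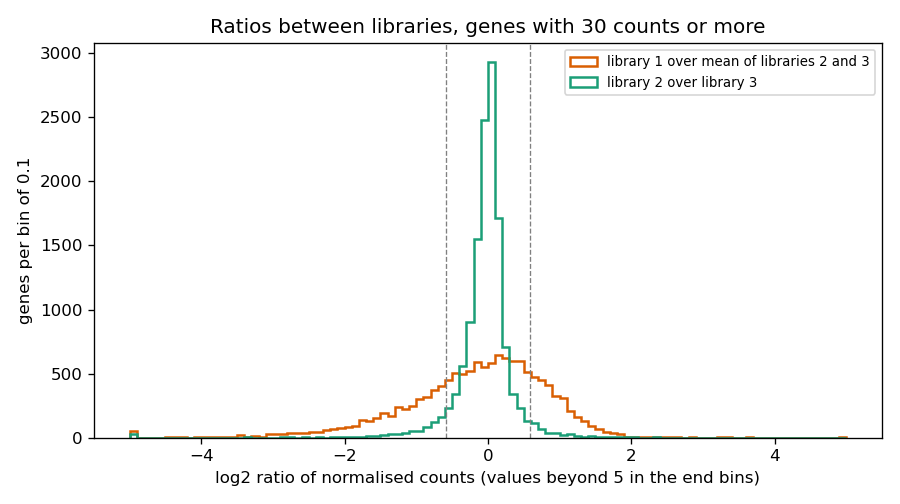
The histogram counts genes per 0.1 of log2 ratio of normalised counts, for library 1 over the mean of libraries 2 and 3 and for library 2 over library 3, with dashed lines at 1.5-fold. The first distribution is broad and the second narrow, as the coefficients of variation of 0.334 over all libraries and 0.0724 for libraries 2 and 3 reflect.

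T cell receptor beta transcripts used a few V genes most. Trbv13-3, on chromosome 6 (41130147 to 41130585), took 31.3% ± 3.03 of the Trbv counts, Trbv31 22.3% ± 3.71, Trbv13-2 17.2% ± 2.58, Trbv29 8.14% ± 2.35 and Trbv12-2 4.78% ± 1.07 (SD, n = 3). The Trbv shares, from 5690, 4911 and 5744 counts in libraries 1, 2 and 3, differed between the libraries (chi-square 354 with 38 degrees of freedom, p = 7.38e-53), in a test that covers counting error only. Random gene sets with like counts differed between these libraries in a like way, with a median of 4.41 against 5.45 for Trbv in the ratio of the distance between libraries 1 and 2 to that between 2 and 3, so a difference specific to receptor genes was not shown. The total variation distance was 13.5% between libraries 1 and 2, 13.8% between 1 and 3 and 2.48% between 2 and 3, and the shares of libraries 2 and 3 alone did not pass the threshold (chi-square 19.7, p = 0.414). Of the Trav genes, Trav14d-3-dv8 took 30.9% ± 3.08, Trav14n-3 23.8% ± 1.89 and Trav14-3 9.64% ± 0.280 (SD, n = 3), and Trav7d-2 and Trav7-2 followed. These Trav genes have close copies, and Trav7d-2 took 5.47%, 0% and 4.40% while Trav7-2 took 0%, 6.30% and 1.505%, so Trav shares are uncertain.

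The transcript estimates gave a leading isoform for most genes examined. A single transcript carried more than 50% of the TPM in 7 of 10 genes. Cd44-203 took 56.0% ± 6.66 of Cd44 and Cd44-207 36.0% ± 6.25 (SD, n = 3). Ptprc, whose spliced forms mark naive and memory T cells, was led by Ptprc-203 at 46.6% ± 5.93 (SD, n = 3). Tcf7-201 took 73.1% ± 0.4995 of Tcf7, Cd28-201 90.3% ± 0.514 of Cd28, Il7r-201 72.2% ± 2.78 of Il7r and Lef1-203 52.9% ± 4.22 of Lef1 (SD, n = 3). Ctla4-201 took 100% of Ctla4 in each library. Ikzf2 was led by Ikzf2-205, a retained-intron transcript, at 52.4% ± 7.27 (SD, n = 3), and without library 1 it no longer passed 50%. Ikzf1-203 at 39.0% ± 7.80 and Foxp1-230 at 21.7% ± 2.34 had the highest mean shares of their genes (SD, n = 3), but not in every library. Ikzf1-204 led in library 1, and Foxp1-228 and Foxp1-218 led in libraries 2 and 3.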

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

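The phiX174 row and the rows with a numeric ID, left out of the gene tests, held counts above the limit that a count of 0 allows, and no explanation is offered for them. The phiX174 genome, a control used in sequencing runs, had 52625 counts in library 1, 44469 in library 2 and 36722 in library 3, or 0.3002%, 0.290% and 0.217% of the expected counts. The rows with a numeric ID, whose identity was not looked up, had 669, 1309 and 1586 counts. The 96 ERCC spike-in rows had 0 counts in each library.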

How the results depend on the processing

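Of the checks of the main results that left out a library, 30 held, 2 moved and 1 weakened. Under other settings 26 held and 6 moved. For mean TPM and count shares the limit was a move of 1 SD of the 3 libraries, which leaving out 1 of 3 cannot reach. Those checks could not fail, so they do not show stability. Ubb, for example, had a mean TPM of 5913 over all libraries and 2897 without library 1. Only the M4 table without library 1 was chosen after the data were seen. The number of genes detected ran from 8889 (TPM of at least 5) to 13271 (mean TPM of at least 1), within 1.5 times of 11694. The effector memory list lay above the naive list in all settings, by 0.11 to 0.56, and never past the threshold.

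Library 1 decided several values. Leaving out each library in turn, the coefficient of variation ran from 0.0724 to 0.407, the genes varying between libraries from 1991 to 9301, and the largest Trbv distance in T cell receptor V gene usage from 2.48% to 13.7%, the lowest in each case without library 1. V genes were chosen anew at 30 counts each time. In the M4 table without library 1 the coefficient was 0.0354. Scaled by the median overdispersion, the number of genes varying between libraries was 2903.

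With only members at a mean TPM of at least 1, 0 helper pairs passed, Th2 minus regulatory T turned from -1.72 to 0.10 and Th17 minus regulatory T from -1.48 to 0.56. This setting drops 6 Th2, 6 Th17 and 1 regulatory T members, those of lowest TPM. With Ptprc as the reference, a more abundant gene, 7 markers of other cells reached 1%. In count shares, the 50 leading genes took 18.9% of TPM, where the cause was not tested. The 40 of them in the M4 table took 0.755% of its counts, part of the fall of abundant genes tested under other observations. The M4 table was not run for results that need TPM or transcripts. A count of 3 set the limit for undetected genes.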

Other observations

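Genes of energy metabolism and survival were widely expressed. All 15 glycolysis genes were detected, with a median TPM of 147, led by Eno1 at 999 ± 309, Aldoa at 802 ± 91.0 and Ldha at 756 ± 105 (SD, n = 3). All 15 fatty acid oxidation genes were detected at a median of 46.1, led by Hadhb at 195 ± 28.1 and Etfa at 114 ± 59.1 (SD, n = 3). Against the geometric mean of libraries 2 and 3, 9 of them were at least 1.5-fold higher in library 1. Cpt1a and Hadha were at least 1.5-fold lower. Of 13 apoptosis genes 12 were detected, led by Bcl2a1b at 702 ± 213 and Mcl1 at 276 ± 177 (SD, n = 3), without Bak1. Of 18 interferon response genes 17 were detected at a median of 24.8, among them Ifi27l2a at 188 ± 52.9 and Irf7 at 185 ± 15.7 (SD, n = 3), without Ifi44.

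The patterns below had been seen in part when their tests were written, and the tests with random gene sets, with reads overlapping gene ends, with receptor complex genes and with M4 percents at a posterior SD of 0 were chosen after the values were seen.

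Library 1 stood apart from libraries 2 and 3, and the tables argue against 3 explanations as the whole cause. Removing a trend on GC content lowered the number of genes over 1.5-fold apart by 0.662%. Removing a trend on transcript length lowered it by 7.60%, although the ratio and length were related (rho = -0.31 across genes). The log2 ratios of 6 receptor complex genes spanned 1.99 against 0.19 between libraries 2 and 3. Cells that express none of these genes would lower them alike, so such cells are the third explanation. Other T cells, or any cells that express some of them, need not do so, and the range does not argue against those. A part from other cells stays open, since the highest median log2 ratio over the 5 marker lists with at least 3 members at a mean TPM of at least 1 was 0.34, under the limit of 0.5 set beforehand, but single markers reached 1.12; duplicate reads stay open too, since the median size of the log2 ratio, regardless of sign, over genes varying between libraries was 0.816 times as large in the M4 counts as in the M21 counts. For another animal or cell pool, the Trbv distance of library 1 from library 2 was 5.45 times that of libraries 2 and 3, above the limit of 3 set beforehand, but 10000 random sets of genes with like counts gave a median ratio of 4.41, so that limit could not separate receptor usage from the general difference. RNA selection and quality were not tested, although ribosomal RNA was lower in library 1, and no biological difference between groups was tested, since the labels give 1 group.

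Abundant genes had fewer counts in the M4 table than in the M21 table, with a median of 6.23% for the 100 genes highest in M21 counts against 56.2% for the lowest 10% of genes. A candidate explanation is that a single read was kept per start position and strand. The bound set beforehand, 2 counts per base, was passed by 8 genes, all D or J segments of at most 54 bases, against 470 genes in the M21 counts. With start positions of reads that overlap a gene's ends allowed, 0 genes passed it in the M4 counts and 456 in the M21 counts. Leaving out reads shared between paralogs was not decided by the test set beforehand. For genes with a posterior SD of 0, rho between the ratio and the count was -0.26, between the limits of that test. Over all 10957 genes rho was -0.24. The test chosen later argues against this explanation for genes with a posterior SD of 0. Their median was 31.2% for the highest 10% by count against 60.9% for the lowest. The explanation stays open for genes with ambiguous reads.

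Igkc stood at a mean TPM of 901 in cells labelled as T cells. B cells are argued against as the source, since the median of Cd79a, Cd79b, Ms4a1 and Cd74 was 0.104% of the Igkc TPM and the highest of them 2.82%. Plasma cells may contribute and cannot be told apart from other sources. Jchain was 7.32% of Igkc, between the limits set beforehand, and heavy chain constant genes summed to 72.1%, mostly Ighm, which is listed as a B cell marker. Of the 8 plasma cell markers 6 were not detected, and the list's median TPM was 0.187, so the case for plasma cells rests on few genes.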
